A study of Mus musculus with 12 samples.

How the data were processed

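Granulocyte-monocyte precursors (GMPs), the bone marrow cells that give rise to granulocytes and monocytes, were collected by fluorescence-activated cell sorting from C57BL/6 mice of 4 genotypes, and their RNA was measured on 12 Affymetrix Mouse Gene 1.0 ST arrays, 3 per genotype. The groups were wild type (WT), Gfi1 knock-out (KO), knock-in of the common form of human GFI1 (wtKI) and knock-in of a variant form of human GFI1 (SNP). RNA was purified with a micro-scale column kit and amplified with a NuGEN kit for very small inputs before biotin labelling, per the labels' protocols. Group and number of each array came from its label. The labels do not say that the arrays of a group are separate mice, so the p-values measure the spread between these samples, which may be in part technical.

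The deposited values are log2 signals made with RMA per the submitters' processing notes; its version and settings are not given in the sources used here. Each of the 105661 lines of the table is a probe set of the exon-level annotation, and the platform annotation pairs 98975 of them with 1 gene symbol, 1703 with several and 4983 with none. Only the lines with 1 symbol were used to name genes, which gave 14201 genes with a median of 5 probe sets, and 2874 of these genes rest on 1 probe set. A RefSeq gene table of the GRCm38.p6 assembly held 14168 of these genes and was used only for current symbols, 1752 of which were updated, and for the order of genes along chromosomes. Every probe set reaches at least 6.14 on the log2 scale on some array, so the table holds a selection made upstream in a way not stated, and genes that are low in all samples are missing from it. For arrays, it is their number that limits the precision.

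One value per gene and array was made from its probe sets by median polish. The plan, made before the data were examined, had assumed 1 probe set for most genes and would have kept the probe set with the highest mean; that choice and the plain mean of the probe sets were run as alternatives. The groups, the 6 comparisons, the tests, the gene lists, the rule for named genes and most of the alternative settings were also fixed before the data were examined.

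Comparisons were tested with limma 3.58.1 in R 4.3.3 (lmFit and eBayes) on all 12 arrays, with Benjamini-Hochberg adjustment over the 14201 genes and a threshold of 0.05. They were KO minus WT, SNP minus wtKI, wtKI minus WT, SNP minus WT, SNP minus KO, and the difference between the variant effect (SNP minus wtKI) and the loss effect (KO minus WT). All errors printed with a log2 difference are standard errors from this fit, with 3 arrays per group, unless called SD. Gene lists were tested with camera at a preset correlation between genes of 0.01 and adjusted over 20 lists within a comparison. Camera with a correlation estimated from each list, and fry, which asks whether the genes of a list move one way on balance, were alternatives. Members of a list were also adjusted over the list alone. The lists held reported Gfi1-repressed genes, the Hoxa and Meis1 leukaemia programme, stem and early progenitor, primary granule, late neutrophil, monocyte, macrophage, dendritic cell and MHC class II, B-lineage, T and NK cell, erythroid, megakaryocyte, and mast cell, basophil and eosinophil genes, cell cycle, ribosome biogenesis, p53 target, interferon-stimulated, immediate-early and stress, and inflammatory cytokine and NF-kB genes, and the genes next to Gfi1. Between 8 and 22 members of each list were measured. Several lists share members (Gata2, for example, is in the stem cell and mast cell lists), and GMPs themselves express most of the primary granule, cell cycle and ribosome biogenesis genes. Sex-linked and housekeeping genes were kept as checks and not tested as lists.

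The genes named were Gfi1 and its relative Gfi1b in each comparison; up to 10 genes per direction that passed the threshold without overlap between the groups, or, where fewer than 5 passed, the 5 with the smallest p, said not to pass; the members of each list that passed and up to 4 with the largest difference; and Hoxa9, Meis1, Csf1, Irf8 and Id2, often described as Gfi1 targets, in KO against WT and SNP against wtKI. Uncharacterised, olfactory, vomeronasal and small RNA genes were left out of the second part. Id2 was not among the genes with a value and is not analysed here. Any other gene or probe set is said to have been chosen after its values were seen.

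The likeness of the variant effect and the loss effect was measured as the correlation of their log2 differences across genes, ranked among the 100 ways of splitting both pairs of groups. Alternatives were median centring, repeated quantile normalization, leaving out the dimmest 30% of genes, testing all probe sets, fitting only the groups compared, a variance trend with a robust prior, array weights, the replicate number as a block, a fold threshold of 1 on the log2 scale, and leaving out each array in turn. Alternatives added after seeing the data were the fit on 10 arrays without KO 1 and SNP 1, both other ways to make a gene value, and the sex of the mouse as a term. The test on the share of sorted progenitors gained a condition on its standard error after its value was seen, which did not change its outcome.

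The fit was tested on simulated arrays made from the real gene means, gene spreads and array spreads, with 200 of 14201 genes changed. In the simulated KO against WT comparison it recovered 32.8% of genes changed by 1 on the log2 scale, 80.6% of those changed by 2 and 97% of those changed by 4, with 4 false calls; in SNP against wtKI the shares were 38.8%, 82.1% and 98.5%, with 13 false calls. In 10 simulations without any change, at most 1 gene was called in a comparison, with or without array weights. On the arrays with changed genes the 22 measured cell cycle genes were also shifted by 1 and were not counted as false calls. The simulated genes were independent of each other, unlike real ones. Changes of all sizes were mixed in the same 200 genes and adjusted together, so the share recovered at each size depends on the others. A shift of 1 over the cell cycle list was called in 6 of 6 simulations, and the same shift over the late neutrophil list, whose genes vary much between arrays, in 4 of 6. The late neutrophil list was tried first as the list that had to be recovered, and the cell cycle list took its place after this was missed.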

Results

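GMPs from wild-type mice, Gfi1 knock-out mice and mice carrying either the common or a variant form of human GFI1 were profiled to find genes that differ with the variant, in relation to acute myeloid leukaemia. GFI1 is a zinc-finger repressor of transcription that favours the granulocyte over the monocyte fate. The groups held 3 arrays each, and 14201 genes had a value.

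Gfi1 was at 5.78, 5.83 and 6.39 (log2) on WT 1 to WT 3, 6.46, 6.91 and 6.70 on the KO arrays, 6.22, 6.50 and 6.26 on the wtKI arrays and 6.07, 6.48 and 6.55 on the SNP arrays. Single probe sets of Gfi1 separated the knock-in arrays from the others. Of its 5 probe sets, 10532126 had a mean of 3.13 ± 0.56 (SD, n = 6) in the knock-in arrays and 6.15 ± 0.62 (SD, n = 6) in the WT and KO arrays, a difference of -3.02 without overlap (exact permutation p = 0.00216, two-sided, the smallest this design allows). Probe set 10532129 went the other way, at 6.96 ± 0.29 against 5.58 ± 0.17, a difference of 1.38 (SD, n = 6; exact permutation p = 0.00216). For 10532130 the difference was 1.04 (exact p = 0.0281), and for 10532127 and 10532125 it was -0.39 and -0.31 (exact p = 0.108 and 0.385). This grouping of the arrays was chosen after the values were seen, and the 5 p-values are not adjusted. On the knock-in arrays 10532126 lay under the 5th percentile of the probe sets of every array (4.39 to 5.65). The size of its difference is therefore not exact. The gene value of Gfi1 was not lower in KO (0.69 ± 0.22 above WT, limma adjusted p = 0.777), so the probe sets may lie outside the deleted part and do not check the KO label. Gfi1b, a related repressor that Gfi1 is reported to repress, was 0.45 ± 0.18 above WT in KO (limma adjusted p = 0.993).

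**Figure D1:**
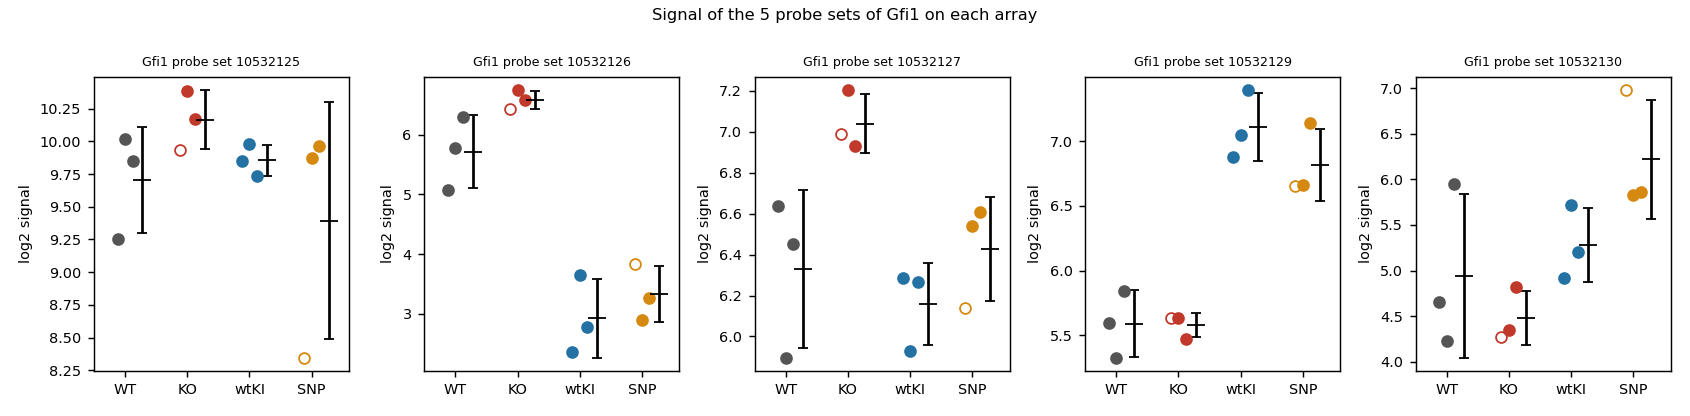
Log2 signal of the 5 probe sets of Gfi1 on each of the 12 arrays, with each group's mean and SD (n = 3) in black and open circles for KO 1 and SNP 1. Probe set 10532126 is lower, and 10532129 higher, on all 6 knock-in arrays than on the 6 WT and KO arrays.

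Across probe sets, KO 1 and SNP 1 had median correlations with the other arrays of 0.70 and 0.633, while those of the other 10 arrays lay between 0.836 and 0.886. Probe sets of the same gene scattered by 0.661 on KO 1 and 0.664 on SNP 1 (log2), against 0.282 to 0.403 on the other 10. Late neutrophil, erythroid and B-lineage genes were far higher on SNP 1 than on the mean of SNP 2 and SNP 3, by medians of 3.68, 3.38 and 2.58, with all 17, 14 and 11 members higher. Ribosome biogenesis genes were lower there in 17 of 17 members, with a median of -1.42. KO 1 differed from the other KO arrays by smaller medians of 0.89, 0.99 and 0.60, and -0.52 for ribosome biogenesis genes. The Y-linked genes Eif2s3y, Kdm5d and Uty were low on WT 3, wtKI 2 and wtKI 3 (Eif2s3y at 2.39, 1.72 and 2.16) and high on the other 9 arrays (Eif2s3y between 7.74 and 8.59). By these genes female mice were present in the WT and wtKI groups only. The 5th percentile of the probe sets lay between 4.39 and 5.65 on the arrays. Genes under it in a group, among them Ifi202b in KO and SNP, Slamf1 in WT and Ly6g and Ebf1 in wtKI, are near background there, and the sizes of their differences are not exact. No pair of arrays shared more than 0.0511% of values equal in every digit of the table.

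KO against WT asked which genes change when Gfi1 is lost. Genes of mast cells, basophils and eosinophils rose together in KO: 12 of 12 measured members were higher, with a median of 0.97 (camera adjusted p = 1.9e-07; adjusted p = 0.634 with an estimated correlation). Fcer1a, the alpha chain of the high-affinity IgE receptor, rose by 3.39 ± 0.79, and Hdc, the enzyme that makes histamine, by 1.51 ± 0.32, both with adjusted p = 0.00737 over the list alone and 0.38 and 0.286 over all genes. Ms4a2, the receptor's beta chain (1.30 ± 0.45), and Prg2, the eosinophil major basic protein (1.24 ± 0.82), were higher without passing. The list's mean lay 1.15, 0.91 and 0.98 above the WT mean on KO 1, KO 2 and KO 3, with the WT arrays at -0.22, 0.62 and -0.40. Its call held without KO 1 (median 0.80, adjusted p = 7.08e-06) and with each other array left out. Immediate-early and stress genes also rose as a list, with 10 of 12 higher, none passing alone, and a median of 0.57. The list had camera adjusted p = 0.00953, and 0.714 with an estimated correlation. Among its members Dusp1, a phosphatase of MAP kinases, was 1.29 ± 0.53 and Egr1 0.98 ± 0.55 above WT. That call was lost without WT 1, KO 1 or KO 2 (adjusted p = 0.0583, 0.0516 and 0.0763).

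Late neutrophil genes split in KO. Mmp8, the neutrophil collagenase, was at 10.23 ± 0.10 in KO and 6.87 ± 0.29 in WT (SD, n = 3), a rise of 3.36 ± 0.72 that passed when adjusted over the list alone (adjusted p = 0.0116) and not over all genes (adjusted p = 0.286). The other secondary granule genes with large differences were lower in KO without passing: Ngp by -3.19 ± 1.15, lactoferrin (Ltf) by -2.40 ± 1.05 and cathelicidin (Camp) by -2.14 ± 1.06. The list as a whole, with 11 of 17 members lower, was not called (adjusted p = 0.408). On the 10 arrays without KO 1 and SNP 1 it was called lower, with a median of -0.68 (adjusted p = 0.000473; adjusted p = 0.459 with an estimated correlation), and Ngp, Ltf and Camp passed over the list alone there (adjusted p = 0.00851, 0.00464 and 0.00851).

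Genes reported as Gfi1 targets were not called as a group in KO, with 8 of 14 higher (adjusted p = 0.198). Hoxa9 was 0.71 ± 0.73 and Meis1 0.65 ± 0.41 above WT, both homeobox genes of leukaemic self-renewal. Csf1 was -0.08 ± 0.46 and Irf8, a monocyte and dendritic cell factor, -0.71 ± 0.25 (adjusted p between 0.888 and 1 for these genes). The Hoxa and Meis1 programme was higher in 6 of 9 members (adjusted p = 0.198) and was called higher on the 10 arrays (median 0.29, adjusted p = 0.026; adjusted p = 0.459 with an estimated correlation). There Hoxa9 (0.78 ± 0.23) and Eya1 (1.54 ± 0.34), a transcription cofactor, passed over this list alone (adjusted p = 0.0303 and 0.0107) and not over all genes (adjusted p = 0.399 and 0.214). Ly86, a monocyte gene, was lower by -1.09 ± 0.28 (adjusted p = 0.0338 over the list alone), and Itga2b, a platelet integrin, higher by 0.73 ± 0.19 (adjusted p = 0.0197 over the list alone, and 0.0507 on the 10 arrays). The monocyte, macrophage, dendritic cell, megakaryocyte, p53 target and interferon lists gave adjusted p = 0.408, 0.882, 0.408, 0.198, 0.445 and 0.693, and the neighbours of Gfi1 on chromosome 5 adjusted p = 0.882.

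No single gene passed over all genes in KO against WT. The smallest p-values belonged to Tulp4 (2.14 ± 0.29), Csf2rb, the beta chain of the GM-CSF receptor (1.17 ± 0.17), Dab2, an endocytic adaptor (1.85 ± 0.28), Grb10, an adaptor of growth factor receptors (1.23 ± 0.19), and Ndrg2 (2.05 ± 0.33). On the lower side they belonged to Pde6c (-1.35 ± 0.19), Adamts6 (-1.48 ± 0.23), Ifi209, an interferon-inducible gene (-1.37 ± 0.24), the lymphocyte receptor Cd96 (-1.44 ± 0.27) and the peptidase Dpp4 (-1.65 ± 0.33), with adjusted p from 0.105 to 0.281. All 10 lay apart between the groups on all arrays. Limma called 0 genes, with 680 at an unadjusted p under 0.05 where 710 are expected by chance. That count was 966 on the 10 arrays without KO 1 and SNP 1, and 794 with only the groups compared. The error of the fit is shared over all 12 arrays, KO 1 and SNP 1 among them. A count under the expected one therefore does not show that no gene changes. With array weights, which rest the KO group mostly on KO 2, limma called 499 genes. In all 11.9% of genes did not overlap between the groups, against 10% by chance. On the 10 arrays 4 genes passed, all higher in KO: Tulp4 (1.80, adjusted p = 0.0225), Mmp8 (3.39, adjusted p = 0.0312), and Ndrg2 (1.96) and Lrig3 (2.04), both with adjusted p = 0.0446. Lrig3 is named after its values were seen. Leaving out KO 3, SNP 1 or SNP 2 alone gave 1, 4 and 1 calls.

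**Figure D2:**
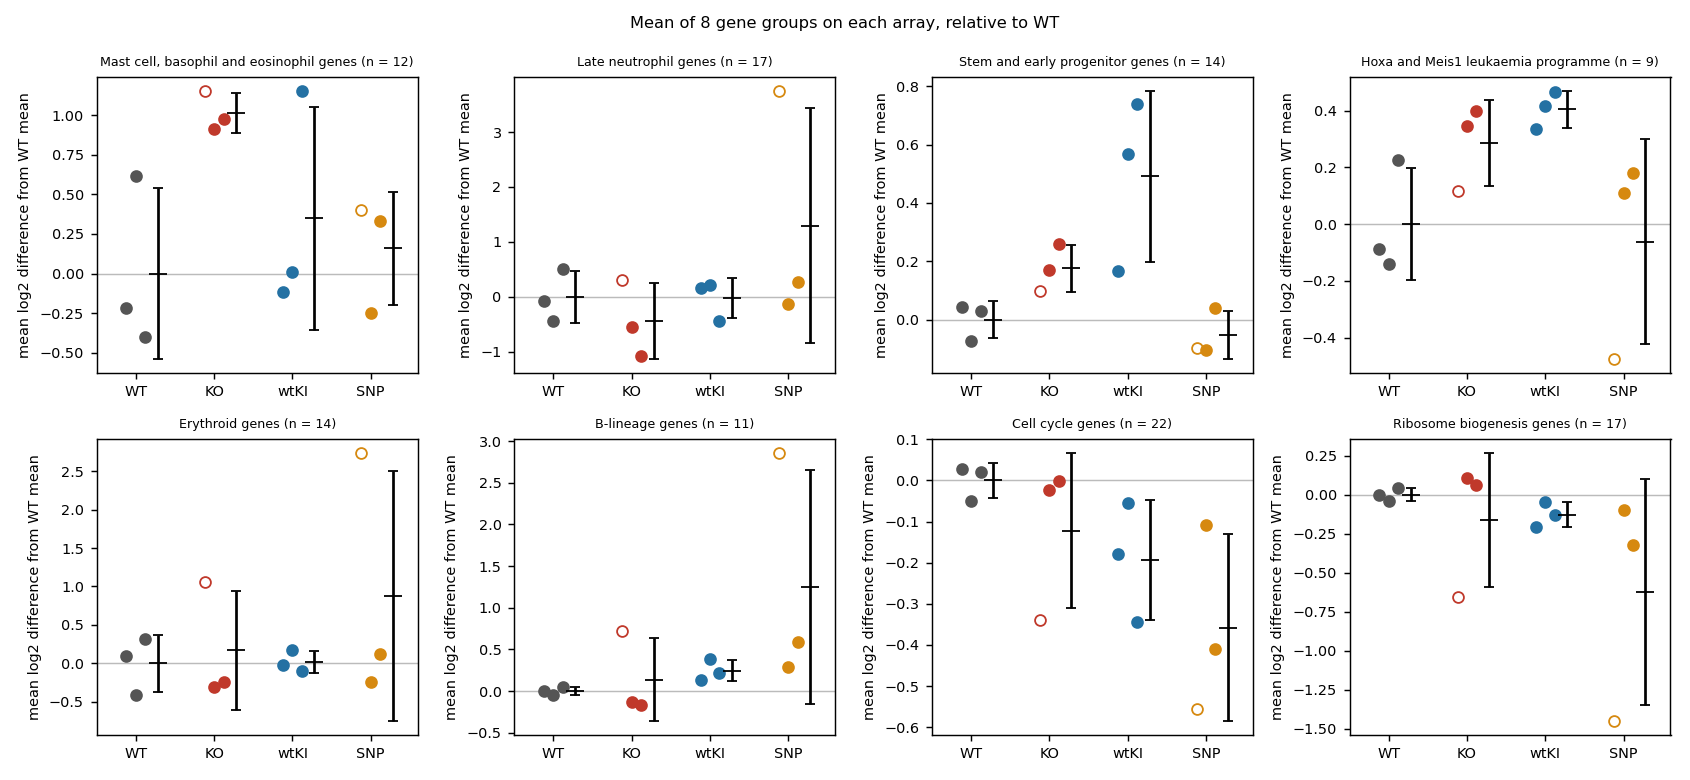
Mean log2 difference from the WT mean over the measured members of 8 gene lists on each of the 12 arrays, with each group's mean and SD (n = 3) in black and open circles for KO 1 and SNP 1. Mast cell, basophil and eosinophil genes lie 0.91 to 1.15 above WT on the 3 KO arrays, and the late neutrophil, erythroid and B-lineage means are highest on SNP 1.

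SNP against wtKI compared the variant with the common form of human GFI1, both as knock-ins, which was the aim of the study. An Rplp0 probe set (10.14 in SNP, 5.44 in wtKI) and Ifi202b (2.25 and 8.96) differed between these groups by all-or-none steps, taken up below. By the Y-linked genes, wtKI 2 and wtKI 3 were female and all SNP arrays male, so these groups also differ in sex. It stays open whether they differ in more than sex and the form of GFI1. Stem and early progenitor genes fell in SNP: 12 of 14 were lower, with a median of -0.41 (adjusted p = 0.000671; adjusted p = 0.0822 with an estimated correlation; fry adjusted p = 0.00741). Slamf1, a surface marker of blood stem cells, fell by 2.31 ± 0.43, Angpt1, a ligand of the Tek receptor, fell by 1.51 ± 0.44, and the transcription factor Gata2 fell by 0.68 ± 0.22 (adjusted p = 0.00313, 0.0384 and 0.0433 over the list alone). Kit and Cd34, which mark progenitors, were lower by -0.91 ± 0.49 and -0.87 ± 0.43 without passing, and by -0.16 and -0.19 on the 10 arrays without KO 1 and SNP 1. The list was called with each array left out and on the 10 arrays (median -0.36, adjusted p = 0.00191; adjusted p = 0.299 with an estimated correlation). There Slamf1 passed over the list alone (adjusted p = 0.00105), and Angpt1 (-0.996) and Gata2 (-0.63) did not (adjusted p = 0.0874 and 0.0991). SNP arrays were at the WT level for this list (-0.10, -0.10 and 0.04 from the WT mean), and wtKI arrays above it (0.17, 0.57 and 0.74). The highest of these, wtKI 2 and wtKI 3, are the female ones. With sex as a term the list was still called (median -0.60, adjusted p = 0.00402), and the Hoxa and Meis1 programme was not (median -0.08, adjusted p = 0.247).

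The Hoxa and Meis1 programme also fell, with 8 of 9 lower and a median of -0.61 (adjusted p = 0.0427; adjusted p = 0.613 with an estimated correlation). Hoxa9 was -1.16 ± 0.73, Eya1 -0.999 ± 0.42, the receptor kinase Flt3 -0.73 ± 0.32 and Meis1 -0.71 ± 0.41, none passing. On the 10 arrays Hoxa9 was at 0.01, Flt3 at -0.37 and Meis1 at -0.42, and the list was not called (median -0.20, adjusted p = 0.16). The call was also lost without wtKI 3, SNP 1 or SNP 2 (medians -0.47, -0.20 and -0.60, adjusted p = 0.134, 0.206 and 0.0841). Csf1 and Irf8 were -0.89 ± 0.46 and -0.32 ± 0.25, and Gfi1 and Gfi1b 0.04 ± 0.22 and 0.08 ± 0.18.

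Late neutrophil genes rose as a list in SNP, with 17 of 17 members higher (median 1.34, adjusted p = 0.000421, and 0.757 with an estimated correlation). Ly6g had the largest difference (3.11 ± 1.09). The list's mean lay 3.76 above WT on SNP 1 and -0.14 and 0.27 from it on SNP 2 and SNP 3. No member of the late neutrophil, B-lineage, T and NK cell or erythroid lists passed over its list alone. B-lineage genes were higher in 10 of 11 (median 0.83, adjusted p = 0.000744; 0.656 with an estimated correlation), with the B-cell factor Ebf1 at 2.96 ± 1.36. T and NK cell genes were higher in 10 of 11 (median 0.23, adjusted p = 0.00377; 0.656 with an estimated correlation), with the interleukin receptor Il7r at 2.58 ± 0.92. Erythroid genes were higher in 12 of 14 (median 0.64, adjusted p = 0.0026; 0.757 with an estimated correlation), with the globin Hbb-b1 at 2.57 ± 1.51. Inflammatory cytokine genes were higher in 9 of 12 (median 0.62, adjusted p = 0.0112; 0.757 with an estimated correlation), with Il1b at 1.87 ± 0.86. The chemokine Ccl9 was lower by -0.85 ± 0.24 (adjusted p = 0.0483 over the list alone, and 0.0541 on the 10 arrays). Ribosome biogenesis genes fell as a list, with 17 of 17 lower and none passing alone (median -0.45, adjusted p = 0.000671; 0.757 with an estimated correlation), with Pes1 at -1.16 ± 0.63. Without SNP 1 the medians of the late neutrophil, erythroid, ribosome biogenesis, B-lineage and inflammatory lists shrank to 0.14, 0.03, -0.07, 0.27 and 0.25, and the lists were not called (adjusted p = 0.985, 0.885, 0.509, 0.457 and 0.457). The T and NK cell median did not shrink (0.29), though that list was not called either (adjusted p = 0.132). Monocyte, macrophage, dendritic cell and megakaryocyte genes were not called on 12 arrays (adjusted p = 0.456, 0.456, 0.17 and 0.982), nor were mast cell genes, with 8 of 12 lower (adjusted p = 0.464). Ly6g was at 1.49, Ebf1 at 1.38, Il7r at 1.16, Hbb-b1 at 1.19, Il1b at 0.46 and Pes1 at -0.46 on the 10 arrays.

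Single genes did not pass over all genes in SNP against wtKI. The lowest p-values were those of Ifi202b, an interferon-inducible gene that is near background in SNP (-6.71 ± 1.13, not an exact size), Fbp1, an enzyme of gluconeogenesis (-2.91 ± 0.49), Ttc8, a ciliary protein (-1.79 ± 0.31), Zdhhc2, a palmitoyltransferase (-2.09 ± 0.36), and Desi2 (-1.31 ± 0.24) on the lower side. On the higher side they were those of Loxl2, a lysyl oxidase (1.48 ± 0.28), Dab1 (1.00 ± 0.19), Prss12 (1.53 ± 0.30), the interferon-inducible GTPase Iigp1 (1.26 ± 0.25) and Spata18 (1.33 ± 0.28), with adjusted p from 0.373 to 0.417. Limma called 0 genes, with 1263 at an unadjusted p under 0.05 (710 expected), and 0 on the 10 arrays (1201 at an unadjusted p under 0.05). The count at an unadjusted p under 0.05 was 423 with sex as a term, 582, 776 and 2402 without wtKI 2, SNP 1 or SNP 2, and 1285 in another split of the arrays. In all 14.6% of genes did not overlap, against 10% by chance. Leaving out WT 1, WT 3 or wtKI 1 gave 2, 1 and 2 calls.

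wtKI against WT compared the common human form with mouse Gfi1. Stem and early progenitor genes rose in wtKI, with 12 of 14 higher and a median of 0.21 (adjusted p = 0.000773; adjusted p = 0.0753 with an estimated correlation). Slamf1 rose by 2.82 ± 0.43 (adjusted p = 0.000554 over the list alone). The Hoxa and Meis1 programme rose as a list, with 9 of 9 members higher, none passing alone, and a median of 0.18 (adjusted p = 0.00423; adjusted p = 0.143 with an estimated correlation); Eya1 was 1.20 ± 0.42, Meis1 0.94 ± 0.41 and Flt3 0.65 ± 0.32 above WT. Both lists were called with each array left out and with sex as a term (adjusted p = 0.00327 and 0.0289). Cell cycle genes fell as a list, with 21 of 22 members lower, none passing alone, and a small median of -0.18 (adjusted p = 0.000773, and 0.706 with an estimated correlation). Among them were the mitotic genes Ccnb2 (-0.39 ± 0.16) and Aurkb (-0.37 ± 0.20). The cell cycle call was lost without wtKI 3 (median -0.08, adjusted p = 0.101). Immediate-early genes rose as a list, with 10 of 12 higher (median 0.40, adjusted p = 0.00643; adjusted p = 0.706 with an estimated correlation), and Jun rose by 1.17 ± 0.27 (adjusted p = 0.0144 over the list alone); this call was lost without WT 1 or wtKI 3 (adjusted p = 0.0502 and 0.077). Mast cell, basophil and eosinophil genes rose as a list, with 9 of 12 higher and none passing alone (median 0.38, adjusted p = 0.0436; adjusted p = 0.706 with an estimated correlation). The list's mean was 1.16 above WT on wtKI 3 and -0.12 and 0.01 from it on wtKI 1 and wtKI 2. Without wtKI 3 the list's median turned to -0.07 (adjusted p = 0.82), and without WT 1 or WT 3 it was 0.20 and 0.15 (adjusted p = 0.358 and 0.422). Without KO 1, KO 2, KO 3 or SNP 2 the adjusted p was 0.0912, 0.0511, 0.0598 and 0.0655. Ly86 was lower by -1.06 ± 0.28 (adjusted p = 0.0404 over the list alone).

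Gfi1 and Gfi1b were 0.33 ± 0.22 and 0.28 ± 0.18 above WT in wtKI. Besides Slamf1, the smallest p-values belonged to Timp3, an inhibitor of metalloproteinases (1.05 ± 0.20), the channel subunit Kcnab1 (1.87 ± 0.36), Gulo (1.28 ± 0.27) and the sterol receptor Nr1h3 (1.62 ± 0.35). On the lower side they belonged to Kctd14 (-2.42 ± 0.44), Lgi3 (-1.35 ± 0.25), Pde6c (-0.80 ± 0.19), the extracellular superoxide dismutase Sod3 (-2.13 ± 0.51) and Pdxk-ps (-0.92 ± 0.22), none passing (adjusted p from 0.562 to 1). Limma called 0 genes, with 435 at an unadjusted p under 0.05 (710 expected), 0 on the 10 arrays (1072 at an unadjusted p under 0.05). In all 12.6% did not overlap, against 10% by chance. Leaving out WT 1 or WT 3 gave 1 call each.

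SNP against WT set the variant against wild type. Cell cycle genes fell as a list, with 21 of 22 members lower and none passing alone (median -0.27, adjusted p = 0.00136; adjusted p = 0.572 with an estimated correlation), with the replication genes Mcm2 and Mcm5 at -0.97 ± 0.32 and -0.94 ± 0.26. This list was called with each array left out and on the 10 arrays (median -0.25, adjusted p = 0.012). Another 8 lists were called, each with adjusted p = 0.572 with an estimated correlation, and each lost without SNP 1. Late neutrophil (adjusted p = 0.00157), B-lineage (0.00136), T and NK cell (0.0162), erythroid (0.0115), inflammatory (0.00648) and immediate-early genes (0.013) rose as lists, with medians of 1.44, 0.91, 0.53, 0.78, 0.59 and 0.73. Without SNP 1 the medians were -0.13, 0.34, 0.28, -0.05, 0.37 and 0.07 (adjusted p = 0.993, 0.154, 0.203, 0.993, 0.154 and 0.677). Ribosome biogenesis (0.000439) and primary granule genes (0.0283) fell as lists, with medians of -0.65 and -0.33, and had medians of -0.25 and -0.11 without SNP 1 (adjusted p = 0.154 each). Of these 8 lists only the B-lineage and immediate-early lists had a member passing over the list alone. Without WT 2 the primary granule and erythroid lists had adjusted p = 0.0947 and 0.0568. Over their lists alone the transcription factors Egr2 (1.18 ± 0.22, adjusted p = 0.00304) and Jun (1.08 ± 0.27, adjusted p = 0.0244) and the B-cell adaptor Blnk (1.35 ± 0.37, adjusted p = 0.0431) rose. The RNA sensor Ifih1 fell by 0.96 ± 0.23 (adjusted p = 0.0249). On the 10 arrays Egr2 and Jun also passed over their lists (adjusted p = 0.00538 and 0.045), and Blnk (0.88) and Ifih1 (-0.77) did not (adjusted p = 0.0523 and 0.103).

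By p, SNP against WT was led by Iigp1 (2.04 ± 0.25), Ugt1a6b (2.04 ± 0.31), Rp1 (2.28 ± 0.36), Grik2 (2.09 ± 0.34) and Kcnab1 (2.26 ± 0.36) on the higher side. The lower side was led by Ndufs5, a subunit of respiratory complex I (-1.80 ± 0.25), Abcf2 (-1.17 ± 0.19), Ttc8 (-1.88 ± 0.31), Pdxk-ps (-1.34 ± 0.22) and Pdcl3 (-0.95 ± 0.16), none passing (adjusted p from 0.0705 to 0.11). Gfi1 and Gfi1b were 0.37 ± 0.22 and 0.37 ± 0.18 above WT. Limma called 0 genes, with 2260 at an unadjusted p under 0.05 (710 expected), 0 on the 10 arrays (2278 at an unadjusted p under 0.05). In all 25.7% did not overlap, against 10% by chance. Leaving out WT 2, KO 1 or SNP 2 gave 1, 2 and 1 calls.

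SNP against KO set the variant against loss of Gfi1. Csf2rb fell by 1.42 ± 0.17 and Zdhhc2 fell by 2.88 ± 0.36 in SNP relative to KO, without overlap between the arrays. They were the 2 genes called by limma (adjusted p = 0.0471 each). Csf2rb was at 8.34 ± 0.10 in KO and 6.92 ± 0.15 in SNP, with WT at 7.17 ± 0.17 and wtKI at 7.51 ± 0.21 (SD, n = 3). Grb10 (-1.45 ± 0.19), Serpina3g (-2.39 ± 0.34) and Vat1 (-1.26 ± 0.19), and on the other side Adamts6 (1.47 ± 0.23), Pde6c (1.19 ± 0.19), Ifi209 (1.40 ± 0.24), Ugt1a6b (1.72 ± 0.31) and Cnksr1 (1.24 ± 0.23), did not pass (adjusted p from 0.0536 to 0.132). Gfi1 was at -0.33 ± 0.22 and Gfi1b at -0.08 ± 0.18, not passing. Both calls were near the threshold: on the 10 arrays their adjusted p was 0.0822. Without WT 1, WT 2, WT 3, KO 1 or KO 2 it was 0.104, 0.06, 0.114, 0.137 and 0.147, and without wtKI 1, wtKI 3, SNP 2 or SNP 3 it was 0.064, 0.0545, 0.0906 and 0.0985. Without KO 3 Csf2rb had adjusted p = 0.062, and Zdhhc2 stayed called. With the replicate block both had adjusted p = 0.132. At an unadjusted p under 0.05 there were 1799 genes (710 expected), and 14% did not overlap, against 10% by chance. With array weights, which rest the KO group mostly on KO 2, limma called 516 genes.

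Mast cell, basophil and eosinophil genes fell as a list in SNP relative to KO, with 11 of 12 members lower (median -0.76, adjusted p = 0.00175; adjusted p = 0.585 with an estimated correlation), and Fcer1a fell by 3.11 ± 0.79 (adjusted p = 0.0273 over the list alone). The call held on the 10 arrays (adjusted p = 0.0118) and was lost without SNP 2 (adjusted p = 0.0741). Late neutrophil genes rose as a list, with 14 of 17 higher (median 1.84, adjusted p = 0.000314; adjusted p = 0.585 with an estimated correlation). Over the list alone Ngp rose by 4.13 ± 1.15, Camp by 3.58 ± 1.06, the calcium-binding S100a9 by 3.37 ± 0.86, Ltf by 3.29 ± 1.05 and Ly6g by 3.23 ± 1.09 (adjusted p from 0.0346 to 0.0432). Without SNP 1 the list was not called (median 0.25, adjusted p = 0.441). On the 10 arrays its median was 0.95 and its adjusted p 0.0546, with Camp at 2.02 and Ly6g at 1.55 (adjusted p = 0.0675 over the list alone), and S100a9 and Ngp were among the members that passed over the list alone (adjusted p = 0.00171 and 0.0149). B-lineage genes rose as a list, with 11 of 11 higher and 1 passing over the list alone (median 0.98, adjusted p = 0.000975; without SNP 1 median 0.27 and adjusted p = 0.16) and ribosome biogenesis genes fell as a list, with 17 of 17 lower and 0 passing (median -0.47, adjusted p = 0.00116; without SNP 1 median -0.06 and adjusted p = 0.434); both were called on the 10 arrays (adjusted p = 0.0174 and 0.00771). With an estimated correlation every list called here had adjusted p = 0.585. Inflammatory genes rose as a list (adjusted p = 0.0102, without KO 2 0.063 and without SNP 1 0.385), as did T and NK cell genes (0.0474). Cell cycle (0.0188), stem cell (0.0474) and primary granule genes (0.0474) fell as lists. Among these only the stem cell list had a member passing over the list alone. Cell cycle genes had adjusted p = 0.0929, 0.146, 0.16 and 0.0855 without KO 2, KO 3, SNP 1 or SNP 3. Stem cell genes had 0.0531, 0.0559, 0.0995, 0.0839, 0.0971, 0.0524, 0.16 and 0.0939 without WT 1, WT 2, KO 1, KO 2, KO 3, wtKI 1, SNP 1 or SNP 2, and 0.0568 with the replicate block. Primary granule genes had 0.0519, 0.0548, 0.168, 0.146, 0.0524, 0.234 and 0.0661 without WT 1, WT 2, KO 2, KO 3, wtKI 1, SNP 1 or SNP 2. T and NK cell genes had 0.0534, 0.0572, 0.0995, 0.0515, 0.146, 0.0524, 0.0568 and 0.48 without WT 1, WT 2, KO 1, KO 2, KO 3, wtKI 1, wtKI 2 or SNP 1. Procr, a stem cell receptor, fell by 0.83 ± 0.22 (adjusted p = 0.0425 over the list alone, and 0.197 on the 10 arrays).

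**Figure D3:**
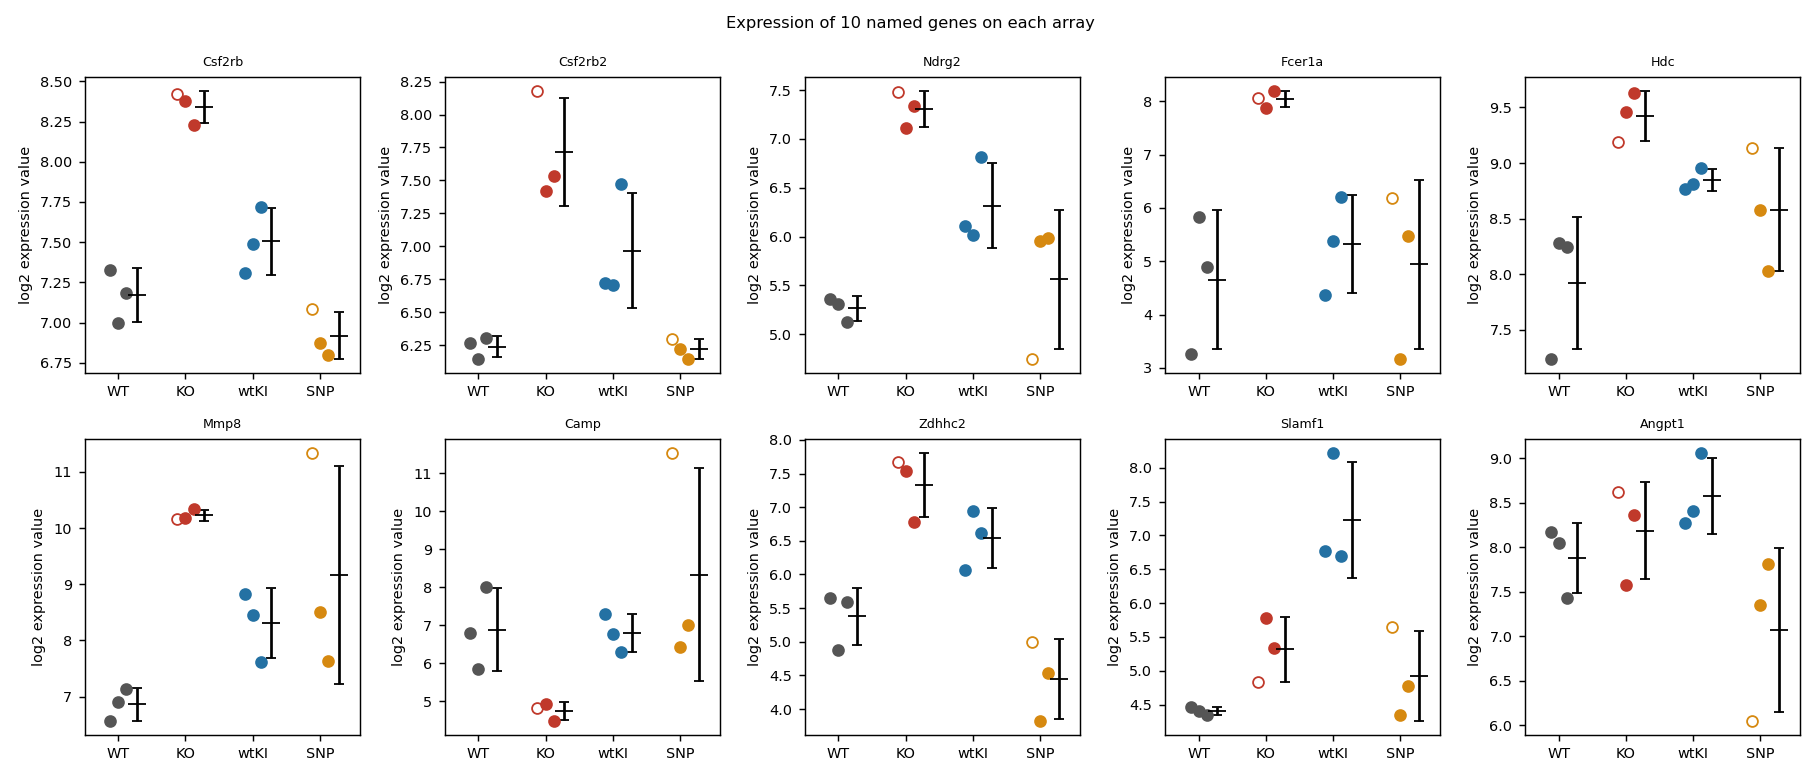
Log2 expression of 10 named genes on each of the 12 arrays, with each group's mean and SD (n = 3) in black and open circles for KO 1 and SNP 1. Csf2rb, Fcer1a, Hdc and Mmp8 lie higher on all 3 KO arrays than on the 3 WT arrays, and Slamf1 lies higher on the 3 wtKI arrays than on the others.

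The test of the difference between the variant effect and the loss effect asked where both effects differ. Stem and early progenitor genes had a lower variant effect than loss effect in 12 of 14 members (median -0.49, adjusted p = 6.19e-05; adjusted p = 0.0345 with an estimated correlation, and 0.301 with it on the 10 arrays). Slamf1 (-3.22 ± 0.61), Angpt1 (-1.81 ± 0.62), Gata2 (-1.21 ± 0.31) and Procr (-1.05 ± 0.31) passed over the list alone. Of these only Slamf1 did so on the 10 arrays (adjusted p = 0.000956, against 0.16, 0.055 and 0.0658). Mast cell, basophil and eosinophil genes did so in 10 of 12 (median -1.26, adjusted p = 6.19e-05; adjusted p = 0.462 with an estimated correlation), with Fcer1a at -3.77 ± 1.12, Ms4a2 at -2.30 ± 0.63 and Hdc at -1.77 ± 0.45, passing over the list alone. Both lists were called with each array left out. The genes with the smallest p were Pde6c (1.99 ± 0.26), Ifi209 (1.94 ± 0.34), Kctd14 (3.23 ± 0.62), Ly86 (1.91 ± 0.39) and Klhl29 (1.28 ± 0.27) on the higher side. On the lower side they were Zdhhc2 (-4.05 ± 0.52), Csf2rb (-1.76 ± 0.24), Csf2rb2, a second beta chain of cytokine receptors (-2.22 ± 0.35), Ndrg2 (-2.80 ± 0.46) and Dab2 (-2.37 ± 0.39), none passing over all genes (adjusted p from 0.0693 to 0.388). Gfi1 and Gfi1b were at -0.65 ± 0.31 and -0.37 ± 0.25. Limma called 0 genes, with 650 at an unadjusted p under 0.05 (710 expected), and 0 on the 10 arrays (1090 at an unadjusted p under 0.05). Leaving out WT 1 or wtKI 1 gave 1 and 3 calls.

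Across genes, which are not independent replicates, the log2 differences of SNP minus wtKI and KO minus WT correlated with r = 0.232, and 44 of 100 splits of the arrays gave an absolute r as large (permutation p = 0.44). Without KO 1 and SNP 1 r was 0.0255 (permutation p = 0.71), and without KO 1 alone it was -0.00807. No gene was called in KO against WT, so the planned count of genes moving the same way could not be made.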

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

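The tests of leaving out 1 array, of the sex of the mice, of the share of sorted progenitors, of Ifi202b against the form of GFI1 and of a chromosome segment were chosen only after the results were seen, as were the fits on 10 arrays.

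For 6 gene lists the variant effect (SNP minus wtKI) and the loss effect (KO minus WT) differed by a test of the difference itself. The median differences were -0.54 for the Hoxa and Meis1 programme (camera adjusted p = 0.00509; 0.171 with an estimated correlation), -0.488 for stem and early progenitor genes (6.19e-05; 0.0345, and 0.301 on 10 arrays), 1.98 for late neutrophil genes (0.000123; 0.72), 0.637 for B-lineage genes (0.00559; 0.72), -1.26 for mast cell, basophil and eosinophil genes (6.19e-05; 0.462) and -0.238 for ribosome biogenesis genes (0.0328; 0.72). Without SNP 1 the late neutrophil, B-lineage and ribosome biogenesis lists had medians of 0.46, 0.25 and 0.02 and were not called (adjusted p = 0.451, 0.542 and 0.848). On the 10 arrays without KO 1 and SNP 1 the late neutrophil list was called (median 0.915, adjusted p = 0.015; 0.59 with an estimated correlation), and the other lists had adjusted p = 0.121 and 0.0946. The ribosome biogenesis list was also lost without WT 1, KO 2, KO 3 or wtKI 2 (adjusted p = 0.0659, 0.292, 0.201 and 0.0994). Splits of the arrays do not exclude chance for the number of lists: 54 of 100 splits gave 6 or more, and the highest other gave 12. For single genes 0 were called, so 100 of 100 splits gave as many by construction, with 2 as the highest other. That count says nothing about chance.

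Late neutrophil genes were higher in SNP than in wtKI by a median of 1.34, and without SNP 1 the median was 0.142. All members, 100%, were higher on SNP 1 than on the mean of SNP 2 and SNP 3, with cathelicidin (Camp) at 11.54, the globin Hbb-b1 at 11.52 and Ly6g at 9.46, while primary granule genes were higher there in 4 of 13. Mature neutrophils, red cells and B-lineage cells in the SNP 1 sort are a candidate source, though a sort for GMPs is meant to remove them. The progenitor markers Kit (6.30, against 8.71 and 8.41 on SNP 2 and SNP 3) and Cd34 (8.55, against 10.69 and 10.45) were low on SNP 1. The scatter between probe sets of a gene on SNP 1 was 1.64 times the highest of the other 10 arrays, so poor amplification of that sample may also contribute, and these readings exclude neither. An effect of the variant on these genes on 1 array of 3 stays open and was not tested.

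Mast cell, basophil and eosinophil genes were higher in KO than in WT by a median of 0.97, a call that rests on the preset correlation between genes (adjusted p = 0.634 with an estimated one). A single unusual array is argued against by the median of 0.797 without KO 1 (adjusted p = 7.08e-06), and the sex of the mice by the median of 0.87 with sex as a term (adjusted p = 3.82e-07). A lower share of the sorted progenitors, replaced by cells of every other type, would raise late neutrophil genes. The late neutrophil mean on KO 2 and KO 3 was -0.812 from WT (standard error 0.39, WT arrays from -0.44 to 0.51) while the mast cell list was at 0.95. Erythroid and B-lineage genes were not raised there either (means -0.31 and -0.24, and -0.13 and -0.17). Loss of Gfi1 may itself lower late neutrophil genes, and the other cells may be of few types, so this list cannot exclude a lower share. On KO 1 a lower share stays open too (late neutrophil mean 0.304, within the WT arrays, and erythroid and B-lineage means 1.06 and 0.72 from WT). More mast cell or basophil precursors among the sorted cells, or a higher level of these genes within GMPs, stay open as hypotheses; loss of Gfi1 may be the cause, and arrays of whole sorted populations do not separate these.

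Some features stepped between arrays in an all-or-none way, noticed after their values were seen. A probe set of the ribosomal gene Rplp0 (10524719) was at 10.36 ± 0.06 in WT, 10.14 ± 0.07 in SNP, 5.42 ± 0.21 in KO and 5.44 ± 0.08 in wtKI (SD, n = 3), and Ifi202b was between 8.71 and 9.35 on the wtKI arrays and at 7.73 on WT 1, against 1.84 to 2.62 on all others. Whether Ifi202b follows the form of GFI1 stays open, since 1 array, WT 1, lies on the other side of its group and a single array decides nothing. A long chromosome segment from another strain that moves gene values would crowd the top genes into a window of neighbours. In KO against WT, 54 of 100 shuffled gene orders gave a window as full. A short segment would escape this test. So would a segment that moves only single probe sets, since genes were ranked by their median-polished values. A strain variant under the Rplp0 probe set cannot be told apart from a smaller or partial real change. The median of its other probe sets in KO minus WT was -1.14 (from -2.02 to -0.03, and -1.57 for a probe set with an SD of 2.58 in KO). In wtKI minus WT it was -0.47 (-2.2, -0.83, -0.1 and 0), against -4.92 for 10524719. In KO minus WT 10524719 was at -4.94, against -2.02, -0.03, -1.57 and -0.72 for the others. The values of KO and wtKI argue against a fall of the whole gene by that size in these groups.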

How the results depend on the processing

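The fits on 10 arrays, with the mean of the probe sets, with the probe set of highest mean and with sex as a term were chosen after seeing the data. Counts are genes called by limma, and the cause was not tested unless stated. KO against WT had 0 calls, and 3 over all probe sets, 1 with only the groups compared, 499 with array weights (259 higher and 240 lower), 4 on 10 arrays and 3 with the mean of the probe sets. SNP against wtKI had 0, and 3 over all probe sets and 1 with only its groups. wtKI against WT had 0, and 2 over all probe sets and 4 with array weights. SNP against WT had 0, and 1 without dim genes and 4 with array weights. SNP against KO had 2, and 1 without dim genes, 0 with only its groups, 5 with the variance trend, 516 with array weights, 0 on 10 arrays, 13 with the mean of the probe sets, 0 with the highest probe set and 0 with sex as a term. The difference of effects had 0, and 1 over all probe sets, 16 with array weights and 2 with the mean of the probe sets. The weights ranged from 0.167 for SNP 1 and 0.22 for KO 1 to 6.83 for KO 2. In simulations of independent genes without any change, the fit with weights called 0 genes in KO against WT and in SNP against KO. This does not show the calls with weights to be real, as KO 2 carries most of the weight of its group (KO 3 had 0.87). At an unadjusted p under 0.05 the comparisons had 680, 1263, 435, 2260, 1799 and 650 genes, and 556, 423, 310, 1527, 1533 and 459 with sex as a term. Leaving out 1 array moved these counts to 509 to 1152, 582 to 2402, 288 to 663, 1392 to 3259, 1273 to 2629 and 480 to 1020. The highest counts in other splits of the arrays were 701, 1285, 413, 1022, 3464 and 1664. Leaving out 1 array gave 0 to 4 calls in KO against WT, 0 to 2 in SNP against wtKI, 0 to 1 in wtKI against WT, 0 to 2 in SNP against WT, 0 to 4 in SNP against KO and 0 to 3 in the difference of effects.

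Called lists numbered 2, 8, 5, 9, 9 and 6 in the same order. With an estimated correlation they were 0, 0, 0, 0, 0 and 1, and with fry 0, 1, 0, 0, 0 and 1. Without dim genes 4 were called in SNP against wtKI and 5 in SNP against KO; on 10 arrays 4 in KO against WT, 1 in SNP against wtKI, 1 in SNP against WT and 5 in SNP against KO; with the highest probe set 1 in KO against WT and 5 in SNP against KO. Leaving out 1 array gave 1 to 2, 1 to 11, 2 to 6, 1 to 12, 1 to 11 and 4 to 10 lists, the low counts in the comparisons of SNP coming without SNP 1. The correlation of the variant and loss effects, 0.232, ranged from -0.00807 without KO 1, where its direction turned, to 0.309 without KO 3. Over all called lists and alternatives, 578 results kept direction and side of the threshold, 194 kept direction only and 8 moved. For named genes, 5298 stayed, 70 came to pass, 31 no longer passed and 23 moved.

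With the replicate number as a block, SNP against KO had 0 calls in place of 2, the mast cell list in wtKI against WT had adjusted p = 0.0622 and the stem cell list in SNP against KO 0.0568, and it ended no other call. Same-numbered arrays correlated from -0.187 to 0.352, with 4 of 18 pairs over 0.1, so over all groups the numbers do not pair the samples. The KO and SNP pairs were 0.352, 0.206 and 0.144, but KO 2 correlated more with SNP 3 (0.218) and KO 3 with SNP 2 (0.312) than with their own number. Probe sets near background limit small differences, and genes low on all arrays are missing from the values.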

Other observations

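The test of the covariance below was set before its result was seen, and the genes named from single probe sets were chosen after their values were seen.

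Csf2rb was higher on each KO array than on any other array. Csf2rb2 was at 7.71 ± 0.41 in KO, 6.24 ± 0.08 in WT, 6.97 ± 0.44 in wtKI and 6.22 ± 0.08 in SNP (SD, n = 3). Ndrg2 was at 7.31 ± 0.18 in KO and 5.27 ± 0.13 in WT, with wtKI at 6.31 ± 0.44 and SNP at 5.56 ± 0.71. These genes were named by their small p in the comparisons above, and Csf2rb2 and Ndrg2 did not pass over all genes on 12 arrays. Among single probe sets, 10396483 of Rhoj, a small GTPase, was higher in KO than in WT by 3.72 ± 0.32 (limma adjusted p = 0.0113 over all probe sets; 0.0198 on 10 arrays). Probe sets of Cdk12 (4.16) and Top2a (2.36) were higher in SNP than in wtKI (adjusted p = 0.0337 and 0.0246; 0.136 each on 10 arrays), and a probe set of the chaperonin gene Cct6a was lower in wtKI than in WT by -3.65 (adjusted p = 0.02). A probe set of Ppfibp2 was lower in KO than in WT by -2.65 (adjusted p = 0.0257; 0.0751 on 10 arrays).

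KO and wtKI differed from the shared WT arrays in like directions across genes, and the hypothesis of a shared effect was tested against simulated unchanged groups. On 10 arrays the covariance of both sets of log2 differences was 0.0455, against a simulated mean of 0.0467 with a range from -0.0196 to 0.101, and r was 0.389 against 0.462. The shared WT arrays alone can give a covariance of this size. Simulated r ranged from -0.464 to 0.92, so a shared effect could also lie within the range. The test therefore shows no shared effect and cannot exclude it.

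With 3 arrays against 3 there are 10 splits, too few for a share under 0.05. Where the real count is 0, every split gives as many by construction. For genes called, the real count and the highest other were 0 and 0 in KO against WT (10 splits gave as many), 0 and 2 in SNP against wtKI (10), 0 and 3 in wtKI against WT (10), 0 and 0 in SNP against WT (10) and 2 and 1 in SNP against KO (1). For gene lists called they were 2 and 3 in KO against WT (2 splits gave as many), 8 and 12 in SNP against wtKI (9), 5 and 4 in wtKI against WT (1), 9 and 12 in SNP against WT (9) and 9 and 12 in SNP against KO (6).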
